A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

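Mlo3-Flag chromatin immunoprecipitation was hybridised to 2 two-colour Agilent arrays of 60-mer probes, 1 for wild-type cells and 1 for clr4 deletion cells. Per the labels, cells grew in rich medium, chromatin was crosslinked and sheared, and both the precipitated DNA (Cy5) and the whole-cell extract DNA (Cy3) were amplified by random-primed PCR. The scanner files hold the intensity of each spot in both colours, which per the file headers was made by Agilent Feature Extraction, version 9.5.1.1 for the wild-type array and version 9.5.3.1 for the clr4 deletion array, with spatial and multiplicative detrending switched on. The headers give the background and dye normalization methods only as codes (7 for background, 6 and 0 for dye), the same on both arrays, and do not say what the codes mean. The scanner's own ratio column is, per the file headers, the log10 of Cy5 over Cy3 processed signal and was used only for its error estimate. The deposited value table holds log2 ratios of Cy5 over Cy3. Set against the scanner values of the same spots, its columns differed by 0.005 at most from the log2 of the processed signals, which settled their scale, their direction (precipitated over whole-cell extract) and that they were not centred. Their medians were 0.0157 (wild type) and 0.09 (clr4 deletion).

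The log2 ratio of the processed Cy5 over Cy3 signals was computed for each probe with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15. Control spots and 207 probes that the scanner software marked as nonuniform or as population outliers on either array were left out. Each array was centred on its median, which was 0.0142 in wild type and 0.092 in the clr4 deletion before centring, with no loess, because many probes of such an array carry signal. Against a median local background of 72.5 (Cy3) and 56.5 (Cy5) in wild type and 79.0 and 62.5 in the clr4 deletion, 43986 and 43979 probes were well above background in both colours, and 0 were saturated. Probes were placed by exact match of their sequence to both strands of the assembly ASM294v3: 40967 had 1 perfect site, 2816 several and 210 none, the last all on the mating-type contig, whose 824 probes were kept in the array's own contig positions. Chromosome coordinates in the text are from this match. The build of the coordinates in the files is not stated there, and those were not mixed with it. Gene names and positions are from the RefSeq annotation of that assembly, in which the product text of tlh2 reads Tlh1.

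A gene's value is the mean over probes whose midpoint lies between the first and last base of its open reading frame, introns included, for genes with 3 or more probes. Its SD is over those probes. Enriched means a log2 ratio of 1 or more. A gene was counted as higher or lower when its difference (clr4 deletion minus wild type) was 1 or more in size and all its probes differed in that direction. With 1 array per group no test was made and no p-value is given. Region medians were set against 10000 random stretches of as many neighbouring probes from the euchromatic tiling of chromosome II, and list medians against 10000 random lists of the same size, matched in 10 classes of whole-cell extract signal for levels and of mean log2 ratio for differences. The percentiles describe these 2 arrays. The strains were hybridised to separate slides and scanned with different software versions, so batch and group cannot be told apart. The profile along genes used genes of 1 kb or more in 10 bins with 500 bp on either side.

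The counting of changed genes was tested on simulated data made from the wild-type profile and the centred real probe differences moved to other positions, with 200 of 895 genes changed. For the comparison of clr4 deletion with wild type it recovered 50 of 50 genes raised by 2 on the log2 scale and 50 of 50 lowered by 2. It recovered 26 of 50 raised by 1 and 25 of 50 lowered by 1, which sits on the threshold. It called 0 of 695 unchanged genes. The moved differences came from these same 2 arrays, which have no replicates. The 0 calls therefore do not measure how often array-to-array noise gives a false call.

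Genes were named by a rule fixed before the data were examined: the 10 with the highest wild-type ratio, the 10 largest increases and 10 largest decreases among genes whose probes all differed in the same direction, clr4 and mlo3, and for each gene list the 2 members with the highest wild-type ratio and the 2 with the largest difference. The lists and the kinds of region were fixed then too. Single windows and noncoding genes within the heterochromatin regions were chosen after their values were seen. There were 20 lists, 11 of them of given symbols, and symbols were matched by name or synonym. Of the given symbols, 1 of 17 meiotic targets, 3 of 28 genes of RNA surveillance and export and 2 of 14 transporters were not found. The subtelomere is represented by the 50 kb at the right end of chromosome II, as no other subtelomere of chromosomes I and II was tiled, and the centromeres by that of chromosome II.

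Alternatives were normexp background correction (limma 3.58.1 under R 4.3.3, offset 50), loess within each array, values not centred, centred on the lower quartile or scaled to equal median absolute deviation, a filter on dim probes, the deposited value table, other probe minimums, medians over probes, other thresholds, probes with 1 perfect site, other extents of the subtelomere, all chosen before the data were examined, and a correction for probe GC content, chosen after they were seen. The whole-cell extract signal, outside the main comparison, was scanned for stretches of 3 or more neighbouring probes whose centred Cy3 signal differed by 2 or more. Plots were drawn with matplotlib 3.10.9.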

Results

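Mlo3-Flag occupancy of chromatin was profiled in logarithmically growing fission yeast by chromatin immunoprecipitation and tiling arrays. Mlo3 is an RNA-binding mRNA export factor of the REF/ALY family, and Clr4 is the histone H3 methyltransferase that builds heterochromatin. There was 1 array of wild-type cells and 1 array of clr4 deletion cells, so there were no replicates and every SD below is over probes or over genes. Each array compared Cy5-labelled immunoprecipitated DNA with Cy3-labelled whole-cell extract DNA, and values are log2 ratios centred on the array's median. Of 43993 genomic probes, 43786 were used. They tiled 2048.9 kb around the centromere of chromosome II, 50 kb at the right end of chromosome II, 50 kb at the left end of chromosome III, a 41.2 kb contig of the mating-type region and short tiles at hrp1, inv1 and nmt1. The tiling held 895 protein-coding genes with 3 or more probes, with a median of 24 probes each. The median processed signal was 1223 (Cy5) and 1136 (Cy3) in wild type, and 1501 and 1333 in the clr4 deletion. Neighbouring probes differed with a noise SD of 0.14 on both arrays, against an SD of 0.73 over all probes in wild type and 0.82 in the clr4 deletion. The number of arrays limits the precision of every comparison.

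The deleted gene itself could not be examined, since clr4 had 0 probes on the array, as had ura4 and ade6. The gene of the tagged protein, mlo3 (SPBC1D7.04), had a log2 ratio of 0.68 ± 0.23 in wild type and 0.47 ± 0.27 in the clr4 deletion (SD over 12 probes), and 1 of its 12 probes was higher in the mutant. Its difference of -0.21 ranged from -0.36 with normexp to -0.12 with loess. Among other usual marker loci, leu1 differed by 0.30 ± 0.19 (clr4 deletion minus wild type, SD over 23 probes) and his3 by -0.03 ± 0.11 (29 probes).

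The wild-type profile showed where Mlo3-Flag signal over whole-cell extract was found along the tiled chromosome. Neither array was of untagged cells, so precipitated signal that does not come from Mlo3 was not measured. Occupancy and enrichment here mean this ratio. Among protein-coding genes, Mlo3-Flag was most enriched over but2 (SPBC3D6.02), with a log2 ratio of 3.42 ± 0.32 (SD over 22 probes, 10.7-fold), and over SPBC409.08, with 3.17 ± 0.38 (32 probes). Next came cwf24, a splicing factor gene (2.36 ± 0.26, 32 probes), gas2, which encodes a cell wall glucanosyltransferase (2.35 ± 0.66, 26 probes), and knh4 (2.30 ± 0.64, 18 probes). The others of the 10 most enriched protein-coding genes were lcf2, wis1, which encodes the stress pathway's MAP kinase kinase, SPBP23A10.11c, sul1 and rtn1, with log2 ratios from 2.01 to 2.25. In all, 87 genes, or 9.72% of those measured, were enriched 2-fold or more. With loess normalization within the array the count was 31, with normexp background correction 166 and with centring on the lower quartile 186.

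Across whole genes the profile of the clr4 deletion resembled that of wild type, and a single gene was higher by a mean of 2-fold or more with all of its probes higher. This was tlh2 (SPBCPT2R1.08c), the subtelomeric gene for a RecQ-type helicase at positions 4526885 to 4532644 of chromosome II (ASM294v3), which went from -0.17 ± 0.34 to 0.92 ± 0.30 (SD over 112 probes). The median levels of its probes were -0.83 and 0.07 with loess and -0.67 and 0.38 with normexp. Its difference was 1.09 ± 0.31, 2.13-fold, with 112 of 112 probes higher. The single gene that was lower by that margin was SPBC21B10.15, which went from 0.44 ± 0.17 to -0.59 ± 0.21 over 6 probes, a difference of -1.03 ± 0.17. In the clr4 deletion 104 genes were enriched 2-fold or more, and 79 of them were also enriched in wild type. With loess 33 genes were enriched in the clr4 deletion and with centring on the lower quartile 216, so the overlap applies to the median-centred values without loess.

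Smaller differences with all probes in the same direction were spread over genes of several functions. Among the 10 largest increases, str1, a gene for a siderophore iron transporter, differed by 0.83 ± 0.16 (37 probes), gas2 by 0.81 ± 0.27 (26 probes), the polyubiquitin gene ubi4 by 0.79 ± 0.15 (23 probes), SPBP23A10.11c by 0.71 ± 0.32, but2 by 0.68 ± 0.20 and the actin gene act1 by 0.63 ± 0.22. The remaining 3 were tif213, SPBP4H10.14c and clg1, between 0.51 and 0.55. The decreases after SPBC21B10.15 were new22 at -0.73 ± 0.10 (5 probes), rpc10 at -0.66 ± 0.18 (5 probes), the kinetochore gene mis13 at -0.56 ± 0.24 (20 probes) and the copper transporter gene ctr6 at -0.55 ± 0.14 (16 probes). SPBPB2B2.18, SPBCPT2R1.04c, dpm2, pch1 and SPBCPT2R1.01c lay between -0.52 and -0.46. Mean probe GC content was 39.6 to 48.9% in the 10 largest increases and 27.5 to 41.3% in the 10 largest decreases. Over euchromatic probes the strain difference correlated with GC content (Pearson's r 0.39). The values of tlh2 and ubi4, and of the subtelomeric genes SPBPB2B2.18, SPBCPT2R1.04c and SPBCPT2R1.01c, are uncertain, because 108 of 112, 20 of 23, 18 of 19, 15 of 17 and 17 of 17 of their probes had more than 1 perfect site in the genome. The sign of these increases and decreases held under the alternatives run for single genes, which did not include probes with 1 perfect site alone, but their size did not. With normexp SPBP23A10.11c differed by 0.34 and but2 by 0.34, rpc10 by -1.09 and mis13 by -0.89, and with both arrays scaled to equal spread but2 differed by 0.28 and gas2 by 0.52. With loess act1 differed by 0.40, tif213 by 0.32, SPBP4H10.14c by 0.27 and clg1 by 0.25, new22 by -0.42, rpc10 by -0.39, ctr6, dpm2 and pch1 by -0.26 each and SPBPB2B2.18 by -0.23, while SPBCPT2R1.04c and SPBCPT2R1.01c differed by -0.76 each. Across the 895 genes, which are not independent replicates, Pearson's r between the arrays was 0.957 and Spearman's rho 0.946, and 97.8% of genes differed by less than 0.5. The call of tlh2 ended with loess, where its difference was 0.85, and with normexp, where it was 1.08 but not every probe was higher. The call of SPBC21B10.15 ended with loess (-0.66), values that were not centred (-0.96), centring on the lower quartile (-0.98), medians over probes (-0.99) and correction for GC content (-0.92).

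**Figure D1:**
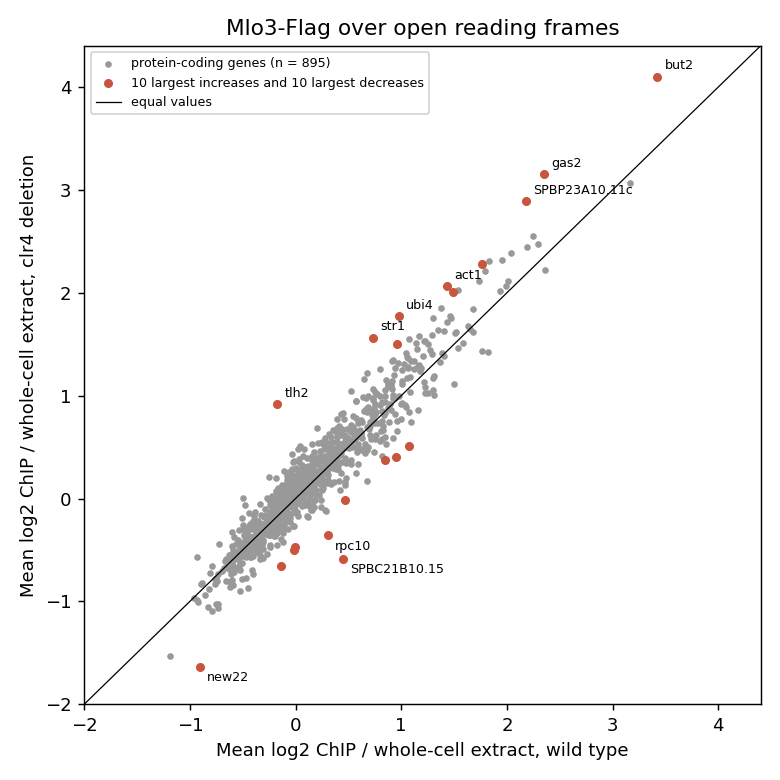
Mean log2 ratio of immunoprecipitated over whole-cell extract DNA for each of 895 protein-coding genes, wild type on the horizontal and clr4 deletion on the vertical axis, with 1 array each; red points are the 10 largest increases and the 10 largest decreases whose probes all differed in the same direction. Most genes lie along the line of equal values, with tlh2 above it at a difference of 1.09.

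The comparison of heterochromatin domains asked whether Mlo3 occupancy differed where Clr4 acts. At the right end of chromosome II the tlh2 probes were higher in the clr4 deletion by a median of 1.12, above every one of 10000 random stretches of as many probes in the euchromatic tiling. The other subtelomeric probes went the opposite way, with a median difference of -0.28 (SD over 878 probes 0.42) that lay below all random stretches, so that the whole 50 kb had a median of -0.22. That median was -0.13 with loess, -0.14 without centring and -0.38 over probes with 1 perfect site, and 676 of the 878 probes outside tlh2 had several sites. In wild type the last 4 windows of 1 kb that were measured, from 4536001 to the chromosome end at 4539804, had medians between 0.06 and 0.17. In the clr4 deletion these windows were lower by medians of -0.64, -0.99, -0.94 and -0.96. The window at 4518001 to 4519000 was higher by 1.04. Within 20 kb of the end the median difference was 0.07, since tlh2 supplies a larger part of those probes.

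The ribosomal DNA at the left end of chromosome III had the lowest occupancy of the regions compared in wild type, and it was lower still in the clr4 deletion. The median went from -1.50 to -2.37 over 450 probes, a median difference of -0.92 (SD 0.51, 1.90-fold lower) that lay below all random stretches. With normexp the wild-type median was -2.26. Of the noncoding genes annotated in the spacers between ribosomal RNA genes, SPNCRNA.6668 and SPNCRNA.6675 differed most. They went from 0.51 ± 0.48 to -1.17 ± 0.10 (SD over 15 probes) and from 0.43 ± 0.38 to -1.19 ± 0.10 (16 probes). The ribosomal RNA gene SPRRNA.47 went from -1.83 ± 0.42 to -2.53 ± 0.22 (70 probes). Every ribosomal DNA probe had several perfect sites, so no single copy can be told from another. Beyond the ribosomal DNA, the left end of chromosome III had a median difference of -0.27 (536 probes), which was 0.06 with loess.

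At the centromere of chromosome II the pericentromeric repeats had a median difference of -0.03 over 650 probes, at percentile 23.4 of the random stretches. The outer repeats held windows in both directions. At 1610001 to 1612000 both 1 kb windows were higher in the clr4 deletion by medians of 0.53 and 0.56, and the windows that start at 1636001 and 1641001 by 0.56 and 0.53. The windows that start at 1607001, 1633001 and 1639001 were lower, by -0.50, -0.55 and -0.54. In the outer repeats 515 of 558 probes had several perfect sites. Windows on the left and right repeats may therefore read the same sequence and are not independent. The innermost repeats had a median difference of -0.23 (92 probes, percentile 2.82). The central core, where the kinetochore forms, had one of -0.20 (140 probes, percentile 2.05). Its levels were -1.04 in wild type and -1.17 in the clr4 deletion. The core was dim, with a centred Cy3 signal of -3.040 in wild type and -4.004 in the clr4 deletion. The random stretches behind these percentiles were not matched on brightness. In the pericentromeric repeats 607 of the 650 probes had several perfect sites, and the 43 with 1 site had a median difference of 0.23, while over all 650 it was -0.14 with normexp, -0.09 with loess and 0.05 without centring. With loess the central core's difference turned to 0.16 and its levels were -0.25 in wild type and -0.05 in the clr4 deletion, and with normexp its difference was -0.57 and its wild-type level -0.38. After correction for probe GC content the differences were -0.15 in the innermost repeats and -0.09 in the central core, and the latter was -0.12 without centring and -0.10 with both arrays scaled to equal spread.

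The mating-type region from mat1 to IR-R had a median difference of 0.02 over 695 probes (percentile 49.9), which turned to -0.11 with loess, -0.04 with normexp and -0.09 over probes with 1 site and was 0.09 without centring. Within it, cenH, the element related to the centromeric repeats, was higher in the clr4 deletion by a median of 0.36 (SD 0.52, 72 probes, percentile 97.9), and the contig's window from 31001 to 32000 by 0.99. The windows of cenH that start at 29001, 30001 and 32001 differed by -0.13, 0.36 and 0.35. The silenced domain between IR-L and IR-R differed by 0.12 (395 probes, percentile 91.2), and the stretch from mat1 to IR-L by -0.08 (300 probes). The latter holds probes beside mat1 whose signal was missing from both colours of the wild-type array, as described below. The strains may therefore differ in their DNA there. The cenH value is uncertain, since 1 of its 72 probes had a single perfect site and 42 had none in the assembly, and it was 0.04 with loess and 0.15 with normexp. The difference between IR-L and IR-R turned to -0.13 with loess and to -0.11 over its 51 probes with a single site, and it was 0.20 without centring and 0.00 with normexp.

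**Figure D2:**
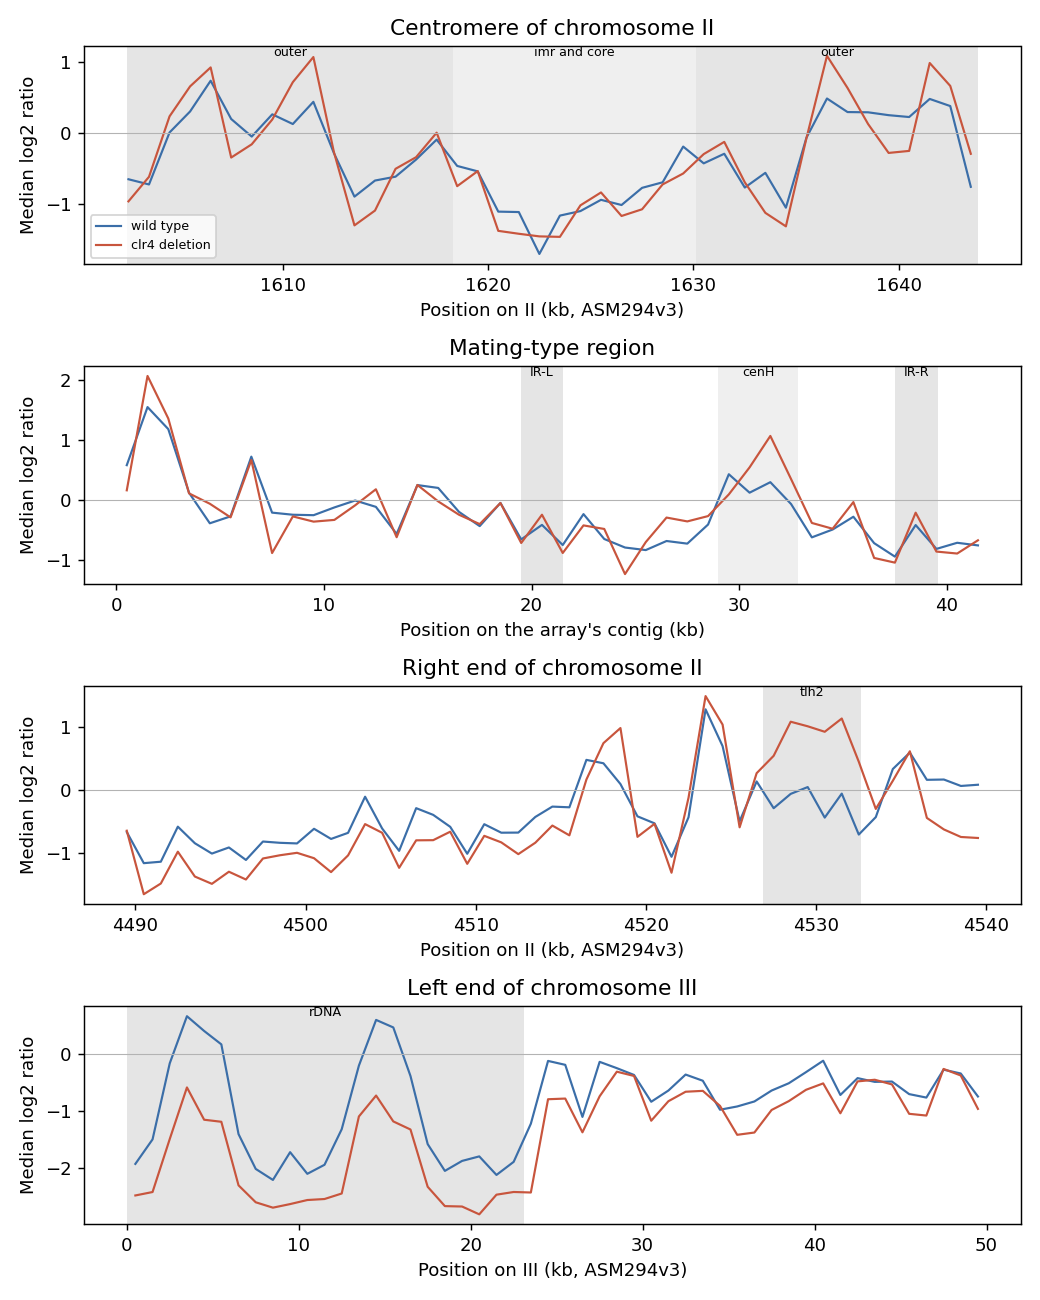
Median log2 ratio in 1 kb windows against position in kb (ASM294v3 for the chromosomes, the array's own contig for the mating-type region), with 1 array per line, wild type in blue and clr4 deletion in red; shading marks the named elements. Over tlh2 the clr4 deletion lies above wild type, and over the ribosomal DNA below it by a median difference of -0.92.

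Along genes of 1 kb or more, Mlo3-Flag occupancy increased from the start codon to bin 8 of 10 in both strains and was lower again in bin 10. Over 528 genes in wild type the mean log2 ratio was -0.01 in bin 1, 0.47 in bin 8, where it was highest, and 0.45 in bin 10. In the clr4 deletion it was 0.01 in bin 1, 0.57 in bin 8 and 0.46 in bin 10. The difference between bin 10 and bin 1 was 0.46 ± 0.57 (SD over 527 genes) in wild type and 0.45 ± 0.56 in the clr4 deletion, and 79.7% and 79.3% of genes were higher in bin 10. In the 75 of these genes that belonged to the most enriched in wild type, this difference was 0.76 ± 0.63 and 0.72 ± 0.56. In the 500 bp downstream of the stop codon the mean over all genes was 0.41 ± 0.74 in wild type and 0.28 ± 0.75 in the clr4 deletion. In the 500 bp upstream of the start codon it was -0.18 ± 0.52 and -0.26 ± 0.51. Both flanks were thus lower in the clr4 deletion, while bin 8 was higher. With loess the difference between bin 10 and bin 1 over all genes was 0.31 and 0.29.

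**Figure D3:**
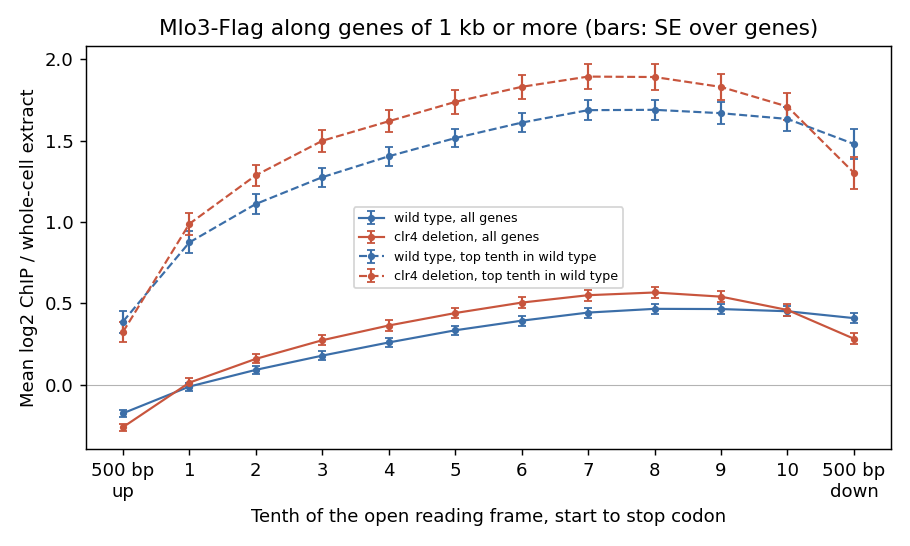
Mean log2 ratio in 10 equal bins from start to stop codon and in the 500 bp on either side, over genes of 1 kb or more; lines are 1 array each, solid for all 528 genes and dashed for the 75 most enriched, and bars are the standard error over genes. Occupancy is highest in bin 8 for all genes on both arrays.

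Between open reading frames, occupancy followed the orientation of the neighbours. The intergenic regions lie between neighbouring coding sequences, so they include the untranslated ends of transcripts. Signal over those ends was not separated from the rest. In wild type, convergent intergenic regions, which lie between gene ends, had a median log2 ratio of 0.40 (2158 probes in 241 regions), tandem regions -0.06 (6153 probes) and divergent regions, which hold promoters, -0.46 (6306 probes). Open reading frames had a median of 0.17. In the clr4 deletion the convergent regions were at 0.21, the tandem regions at -0.20, the divergent regions at -0.53 and open reading frames at 0.26. The median difference was -0.19 ± 0.29 in convergent regions and 0.07 ± 0.25 in open reading frames (SD over probes). The mean probe GC content was 29.49% in convergent regions and 39.13% in open reading frames. In probes of 25 to 30% GC the strain difference was -0.0858, and in those of 35 to 40% it was 0.0435. Part of the contrast between these classes therefore cannot be told from probe GC content.

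Across the gene lists, medians spanned a wider range in level of Mlo3 than in strain difference. Genes without introns were more occupied in wild type than genes with introns, with median log2 ratios of 0.29 (465 genes) and -0.09 (430 genes), above and below all of 10000 random lists matched on whole-cell extract signal. The 2 lists divide the same measured genes, so their percentiles are not independent. The random lists were not matched on GC content, and probes in introns were counted. The strain difference was 0.08 for intronless genes (percentile 99.9 of lists matched on mean occupancy) and -0.01 for intron-containing genes (percentile 0.0). Without centring it was 0.16 and 0.07. With loess the wild-type level of intronless genes was 0.11 and their strain difference 0.02. SPBC409.08 and prp38 (1.76 ± 0.43) were the highest intron-containing genes in wild type. The 2 Tf2 retrotransposons, Tf2-9 and Tf2-10, were enriched at 1.04 in wild type and stood at 0.89 and 0.91 in the clr4 deletion, with 64 of 65 and 66 of 67 probes shared with other sites. Their differences of -0.16 and -0.13 were -0.47 and -0.45 with loess. Of the 12 subtelomeric genes, 11 were lower in the clr4 deletion and tlh2 was the other one, with a median difference of -0.29, or -0.19 with both arrays scaled to equal spread.

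Glycolytic genes were the list with the highest occupancy among those of 3 or more measured genes, and all 4 measured members were higher in the clr4 deletion. Their median was 1.11 in wild type and 1.62 in the clr4 deletion, with a median difference of 0.48 at percentile 99.8 of lists matched on mean occupancy, led by eno101 at 0.54 ± 0.36 (27 probes) and pfk1 at 0.49 ± 0.16 (57 probes), while fba1 had the highest wild-type level at 1.73 ± 0.69. Their median difference was 0.17 with loess and 0.30 after correction for the GC content of the probes. Of 25 ribosomal protein genes, 20 were higher in the clr4 deletion, with a median difference of 0.12 (percentile 93.6), and rpl4302 (0.43 ± 0.21) and rps001 (0.35 ± 0.19) differed most. After that correction the median was -0.03, and with loess it was 0.00. Of 4 chaperone genes 3 were higher (median 0.24, percentile 90.5, but 0.08 with normexp and 0.11 with loess), with sks2 at 0.42 ± 0.22 and mas5 at 0.25 ± 0.26. Among all measured genes, 324 of 465 without introns and 212 of 430 with introns were higher. Counts of higher genes in lists of 3 or 4 members therefore show little by themselves. The 3 histone genes hhf2, hht2 and pht1 were all higher (median 0.22, percentile 96.3), by 0.12, 0.22 and 0.22, and the correction brought their median to 0.05 and hhf2 to -0.01. With loess eno101 differed by 0.25, pfk1 by 0.23, fba1 by 0.11, rpl4302 by 0.20, rps001 by 0.12 and sks2 by 0.21, and with normexp mas5 differed by 0.04.

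Genes of meiosis, mating and RNA pathways showed smaller medians. The 4 measured meiotic targets of the RNA elimination factor Mmi1 had a median difference of 0.03 (percentile 38.2), which turned to -0.13 with normexp, with mei4 at 0.04 ± 0.23, spo5 at -0.08 ± 0.16 and rec8 at 0.24 ± 0.14. The 4 genes of mating and sexual differentiation had -0.03 (percentile 16.8), which turned to 0.05 without centring, with isp4 at 0.24 ± 0.16, rep1 at -0.11 ± 0.22 and gpa1 at -0.11 ± 0.17. The 4 RNA polymerase II subunit genes had -0.10 (percentile 7.85), or -0.02 without centring. In this list rpc10, entered under its synonym rpb12, encodes a subunit shared by all nuclear RNA polymerases, and rpb1, the gene of the largest subunit, differed by 0.45 ± 0.24 (111 probes). Lists with 1 or 2 measured members gave tas3 at 0.12 ± 0.14 and clr1 at 0.00 ± 0.16 among heterochromatin factors, mex67 at 0.17 ± 0.17 beside mlo3 in RNA surveillance and export, nmt1 at 0.11 ± 0.14 beside str1 among nutrient-responsive genes, and tif512 at 0.17 ± 0.15 among translation factors. The one measured entry of the transporter list, any1 (0.10 ± 0.15), was matched through its synonym can1 and encodes an arrestin-related protein, not a transporter. With normexp the differences of any1, mei4 and clr1 turned to -0.11, -0.18 and -0.09, and with loess those of nmt1 and mex67 turned to -0.11 and -0.00, while isp4 differed by 0.04, rpb1 by 0.26, gpa1 by -0.20 and tif512 by 0.08. With normexp spo5 differed by -0.28, rec8 by 0.42, rep1 by -0.33 and tas3 by 0.21.

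Noncoding genes outside the heterochromatin domains were on balance lower in the clr4 deletion. On the centred values, regions between open reading frames were lower too, with median differences of -0.19 (convergent), -0.12 (tandem) and -0.07 (divergent). Centring lowered each of these differences, as the array medians before it were 0.0142 in wild type and 0.092 in the clr4 deletion. The sign of the divergent value depends on that choice. On the centred values, lower signal was thus not particular to noncoding genes. Of 35 tRNA genes 28 were lower, with a median difference of -0.13 (percentile 0.03), and SPBTRNATRP.03 (-0.81, 1 probe) and SPBTRNATYR.02 (-0.68, 2 probes) differed most, both on probes with several sites, and with loess each differed by -0.08. SPBTRNAPRO.07 and SPBTRNAPRO.05 had the highest wild-type levels, 0.74 and 0.71. Of 15 snoRNA genes 12 were lower, with a median difference of -0.11 (percentile 2.68), among them snoU14, at 1.02 ± 0.16 in wild type and 0.53 ± 0.12 in the clr4 deletion, and SPNCRNA.1709 at -0.59 ± 0.12, while snR33 differed by -0.08 ± 0.20. The snRNA gene snu1 differed by -0.25 ± 0.12. Of 348 other noncoding genes 238 were lower, with a median difference of -0.10. The most occupied of them in wild type, SPNCRNA.5100 (2.37 ± 0.08) and SPNCRNA.5825 (2.35 ± 0.30), stood at 1.99 and 1.77 in the clr4 deletion, and SPNCRNA.5189 (-0.67 ± 0.06) and SPNCRNA.5340 (-0.64 ± 0.10) differed most. SPNCRNA.5100 (1262175 to 1262406) lies just beyond the stop codon of rtn1 (at 1262678), and SPNCRNA.1709 (from 1676220) just beyond that of rpc10 (at 1675979). Signal of these 2 noncoding genes cannot be told from that of rtn1 and rpc10. With loess the median differences of the tRNA, snoRNA and other noncoding genes were -0.02, -0.02 and 0.00, and without centring they were -0.05, -0.03 and -0.02. Correction for GC content took the tRNA median to -0.25, and normexp took that of the other noncoding genes to -0.19. The differences of single genes also depended on the setting: that of snoU14 was -0.12 with loess and -1.08 with normexp, that of SPNCRNA.5100 -0.02 and -1.16, that of SPNCRNA.5825 -0.15 and -1.11 and that of SPNCRNA.5340 -0.34 and -1.14, and that of SPNCRNA.5189 was -0.28 and that of snu1 -0.13 with loess, while those of SPNCRNA.1709 and snR33 were -0.89 and -0.36 with normexp.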

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

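Of the tests in this part, those of the other copies of tlh2 and all those of the missing signal beside mat1 were chosen only after the result was seen, and the GC correction behind the tests of probe GC content was chosen after seeing the data. The whole-cell extract DNA, which no comparison of binding used alone, differed by 2 or more (log2, centred Cy3 signal, clr4 deletion minus wild type) in 7 stretches of 3 or more neighbouring probes.

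The largest difference lay beside mat1, the expressed mating-type locus, at positions 2115411 to 2115670 of chromosome II, where Cy3 was higher in the clr4 deletion by 8.46, and the contig's own probes, at 2115397 to 2115656, gave 7.93. In wild type the median Cy5 signal of the stretch was -8.43 and in the clr4 deletion 1.03, so the sequence was missing from both colours of the wild-type array. A first test for failed spots, which asked for all 10 probes of both tilings to be missing, found 9 and left that open. The probe that was not missing was the outermost, starting at 2115397, while those missing began at 2115411. A test chosen after the first found that 100% of the 9 probes on the whole array that were missing in wild type alone lay in this stretch, which argues against spots failing at random. The values are consistent with DNA missing from the wild-type strain, such as another mating-type arrangement, but the strains' genotypes at mat1 are not in the labels, and a difference between slides at this place stays open.

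The other 5 stretches were smaller. At 1949411 to 1949670 of chromosome II, within lsd90, Cy3 was higher in the clr4 deletion by 2.58, with a probe GC content of 60.7%. Cy3 was lower by -2.35 at 1867711 to 1867870, by -2.58 at 2828561 to 2828720 and by -2.21 at 4515651 to 4515810 of chromosome II, with probe GC contents of 14.4%, 14.4% and 9.44%, and by -2.59 at 21011 to 21170 of chromosome III, with 21.7%. Across euchromatic probes, which are not independent replicates, the Cy3 difference correlated with GC content (Pearson's r 0.42). No explanation was tested for single stretches.

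The tlh2 gene was higher in the clr4 deletion by a median of 1.12. After correction for probe GC content its difference was 1.09, and the Cy3 signal there differed by -0.078 while Cy5 differed by 0.94, which argues against GC content and against a change in whole-cell extract signal as the whole cause. Signal from other copies of this gene family at other chromosome ends cannot be told apart, because 4 of the 112 probes had 1 perfect site, and these gave 1.05. A difference between the slides, and the loss of Clr4 itself, also stay open, as each strain had 1 array.

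The ribosomal DNA was lower in the clr4 deletion by a median of -0.92. With loess its difference was -0.98 and after correction for GC content -0.93, which argues against a brightness-dependent dye response and GC content as the whole cause. Its Cy3 signal was lower by -0.38 and its Cy5 signal by -1.32, and a rise in whole-cell extract signal is thereby excluded. The slides and the strain stay open for the same reason as for tlh2, and a difference in the number of repeats was not tested.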

How the results depend on the processing

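All alternatives were chosen before the data were examined, except the correction for probe GC content, which was chosen after seeing the data. Values below are median differences (clr4 deletion minus wild type, log2) unless a level, a gain (bin 10 minus bin 1), an r or a count is named. For 32 results of the comparisons the alternatives gave 328 values, of which 223 stayed within the spread of the value or within 1.5 times the count, 99 moved further, including changes of sign where the value lay within its spread, and 6 others changed sign. For 66 named genes, 726 values gave 626 within the spread, 97 that moved and 3 that changed sign, and for 31 levels, 307 values gave 235, 63 and 9. For a named gene with more than 1 probe the spread was the SD over its probes. Some settings could hardly move a value, as given below, so these totals overstate stability. The cause was not tested for any change below, unless one is named. The tlh2 probes stayed higher by 0.88 or more and the ribosomal DNA lower by -0.74 or more in size under every alternative that gave them a value.

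With normexp background correction the counts were 166 for enriched genes in wild type, 0 for genes higher in clr4 deletion and 2 for genes lower in clr4 deletion. With normexp background correction the sign changed, to -0.0011 for lcf2 and -0.057 for wis1. With normexp background correction the values moved to 0.952 for Pearson's r across genes, -0.14 for pericentromeric repeats, -0.57 for central core, -0.041 for mating-type region, 0.0005 for the IR-L to IR-R difference, 0.15 for cenH and -1.07 for rDNA. Others moved to -0.36 for left end of III, 0.63 for gain along genes in wild type, 0.54 for gain along genes in the clr4 deletion, 0.078 for ribosomal proteins, 0.028 for intronless genes, 0.33 for glycolytic genes and 0.082 for chaperones. Others moved to -0.13 for Mmi1 targets, -0.096 for tRNA genes, -0.19 for other noncoding genes, 1.05 for convergent minus divergent regions in wild type and 0.88 for convergent minus divergent regions in the clr4 deletion.

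With loess within each array the counts were 31 for enriched genes in wild type, 33 for enriched genes in clr4 deletion, 0 for genes higher in clr4 deletion and 0 for genes lower in clr4 deletion. With loess within each array the sign changed, to 0.16 for central core, -0.13 for IR-L to IR-R, 0.058 for left end of III, -0.027 for wild-type level of ribosomal proteins and -0.0031 for mex67. With loess within each array the values moved to 0.951 for Pearson's r across genes, -0.089 for pericentromeric repeats, -0.11 for mating-type region, 0.038 for cenH, -0.13 for subtelomere, 0.88 for tlh2 probes and 0.31 for gain along genes in wild type. Others moved to 0.29 for gain along genes in the clr4 deletion, 0.0014 for ribosomal proteins, 0.022 for intronless genes, -0.24 for subtelomeric genes, 0.17 for glycolytic genes, 0.11 for chaperones and -0.022 for tRNA genes. Others moved to -0.022 for snoRNA genes, -0.0002 for other noncoding genes, 0.62 for convergent minus divergent regions in wild type and 0.55 for convergent minus divergent regions in the clr4 deletion.

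Without centring the counts were 0 for genes lower in clr4 deletion. Without centring the values moved to 0.050 for pericentromeric repeats, 0.095 for mating-type region, 0.20 for IR-L to IR-R, -0.14 for subtelomere, -0.84 for rDNA, -0.19 for left end of III and 0.20 for ribosomal proteins. Others moved to 0.072 for intron-containing genes, 0.16 for intronless genes, -0.21 for subtelomeric genes, -0.051 for tRNA genes, -0.031 for snoRNA genes and -0.018 for other noncoding genes. With centring on the lower quartile the counts were 186 for enriched genes in wild type, 216 for enriched genes in clr4 deletion and 0 for genes lower in clr4 deletion. With centring on the lower quartile the sign changed, to 0.17 for pericentromeric repeats level, wild type, 0.14 for pericentromeric repeats level, clr4 deletion, 0.051 for mating-type region level, wild type, 0.13 for mating-type region level, clr4 deletion, 0.026 for IR-L to IR-R level, clr4 deletion, 0.30 for wild-type level of intron-containing genes and 0.20 for wild-type level of tRNA genes. With centring on the lower quartile the values moved to -0.17 for subtelomere, 0.17 for ribosomal proteins, 0.045 for intron-containing genes, 0.13 for intronless genes, -0.24 for subtelomeric genes, -0.078 for tRNA genes and -0.046 for other noncoding genes. With both arrays scaled to equal median absolute deviation the values moved to -0.15 for subtelomere, -0.74 for rDNA, -0.19 for left end of III, 0.49 for gain along genes in wild type, 0.016 for intron-containing genes, 0.050 for intronless genes and -0.19 for subtelomeric genes. Others moved to -0.056 for other noncoding genes.

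With a gene's median over probes the counts were 0 for genes lower in clr4 deletion. With a gene's median over probes the values moved to 0.004 for intron-containing genes and -0.33 for subtelomeric genes. With only probes of 1 perfect site the sign changed, to -0.11 for IR-L to IR-R. With only probes of 1 perfect site the values moved to 0.23 for pericentromeric repeats, -0.095 for mating-type region and -0.38 for subtelomere. With a subtelomere of 20 kb the sign changed, to 0.070 for subtelomere and 0.10 for subtelomere level, clr4 deletion. After the correction for probe GC content the counts were 0 for genes lower in clr4 deletion. After the correction for probe GC content the sign changed, to -0.027 for ribosomal proteins. After the correction for probe GC content the values moved to -0.027 for intron-containing genes, 0.032 for intronless genes, 0.30 for glycolytic genes, 0.055 for histones, -0.25 for tRNA genes, -0.063 for other noncoding genes and 0.81 for convergent minus divergent regions in the clr4 deletion. With enrichment from 1.5-fold the counts were 192 for enriched genes in wild type and 208 for enriched genes in clr4 deletion. With enrichment from 3-fold the counts were 24 for enriched genes in wild type and 35 for enriched genes in clr4 deletion. With differences from 1.5-fold the counts were 7 for genes higher in clr4 deletion and 3 for genes lower in clr4 deletion. With differences from 3-fold the counts were 0 for genes higher in clr4 deletion and 0 for genes lower in clr4 deletion. With a Cy3 difference of 1 the counts were 79 for stretches with a Cy3 difference.

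The level changes under centring on the lower quartile follow from its construction, which adds a constant to each array. Within 20 kb the tlh2 probes make up a larger part of the subtelomere by construction. No paired analysis was possible because each group had 1 array, so that leaving 1 out was also impossible. The ribosomal DNA had no probe with 1 perfect site and gave no value there, and cenH had 1 such probe, which shows nothing about stability. A subtelomere of 100 kb added no probes, the filter on dim probes removed 19 probes and the deposited values differed from the scanner's by 0.005 at most. These settings therefore tested little. Other probe minimums only choose which genes are kept and could not change the value of a single gene, so such values stayed within the spread by construction. Lists with fewer than 3 measured genes are covered by their named genes. Across the array as a whole signal over background limits little, since 43986 and 43979 of 43993 probes were well above background in both colours. That count says little about dim regions such as the central core, whose difference was 0.16 with loess and -0.57 with normexp.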

Other observations

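Over euchromatic probes, which are not independent replicates, the difference between the strains correlated with probe GC content (Pearson's r 0.39). The log2 ratio itself correlated with GC content at 0.20 in wild type and 0.33 in the clr4 deletion. The array of the clr4 deletion had the wider spread, with a median absolute deviation 1.11 times that of wild type.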
